A study of Mus musculus with 6 samples.

How the data were processed

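The data were 6 libraries from left atria of adult CD1 mice, 3 with FOG2 overexpression and 3 wild type, grouped by the titles and genotypes in the labels. Per the labels' protocols, total RNA was depleted of ribosomal RNA and of polyadenylated RNA and made into libraries with a TruSeq RNA v2 kit, a kit that does not mark strand. The submitters' processing notes name STAR, HTSeq (version 0.6.0), edgeR and deepTools and the mm10 build, with no roles or order. The labels do not say whether replicate numbers were shared by litter or day. The p-values of the authors' comparison measure only the spread between these libraries. Those of the list, rotation and shuffle tests compare features with other features and measure no spread between libraries.

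Each of the 34518 rows of the authors' deposited table gave a feature, its position and strand, a log2 fold change of FOG2_OE over WT, a log2 CPM, a likelihood ratio score, a p-value and an adjusted p-value, all from the authors' comparison. The table also had 6 columns named for the samples. Within each group these columns were constant multiples of each other for every feature above 0, with a largest relative spread of 1.8e-14. They were therefore read as fitted values of the authors' model, which differ between replicates only by library size, and not as counts. The edgeR quasi-likelihood fit planned before the data were examined could not be run on them, nor could other count tests. The authors' deposited table, with its p-values as the authors computed them, was used as the main result in its place. No replicate spread, left-out replicate, replicate block, other split of the samples or set test with an estimated correlation could be computed.

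What was computed here starts from those values. Effective library sizes came from the fitted values, the log2 fold changes and the log2 CPM of 765 features above 300 fitted counts in both groups. For each feature the negative binomial dispersion was solved at which the fitted values give the deposited likelihood ratio, for ratios of at least 0.1, and was taken from features of like abundance otherwise. The dispersion gave the implied standard error of the log2 fold change and calls under another scale between the groups. At the deposited scale the recomputed calls were the same 2007 features. Solving the dispersions from the deposited ratios fixes this outcome, so that it does not check them. The median biological coefficient of variation was 50.0%, and 61.3% for features under 10 fitted counts against 21.5% for those of at least 1000. The median implied standard error was 0.96 and 0.26 in these ranges, so that changes of scarce features are imprecise. Fitted values are given as CPM of the effective library. Where a group stood at 0 the fold is a lower bound, with a floor of 3 counts over the group, and floors cover counting error only. In all, 370 features stood at 0 in FOG2_OE and 151 in WT.

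The procedure was tested on simulated counts for the comparison of FOG2_OE with WT (34517 features, 200 changed). The dispersion was recovered with a median error of 0.30%. The likelihood ratio test called 11% of the features changed 2-fold and 68% of those changed 4-fold, with 9 unchanged features called. Changes were planted only in features with at least 20 expected counts per library on average, while 76.3% of the listed features lay under 20. The test was given the dispersions used for the simulation, so that errors of estimated dispersions were not covered. On simulated statistics with a correlation of 0.7 between neighbours, the rotation test found 20 of 20 moved lists and 11 of 180 unmoved ones, and camera 20 and 57.

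Features were placed on GENCODE M21, which uses the same build. Starts in the table count from 0: of 102 symbols also found in a RefSeq table of GRCm38, 96 had a start 1 below the RefSeq start. Positions are printed counting from 1. A feature overlapping several genes is named by the shortest protein-coding gene with a symbol of its own. Strands are those of the table. They are not taken as measured by the reads, since the kit named in the labels does not mark strand. Clusters joined features called in the same direction with gaps of at most 100 kb.

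Gene lists (25) covered rhythm channels and calcium handling, atrial, ventricular, sarcomere, stress and mitochondrial genes, cardiac transcription factors, genes named for atrial fibrillation loci, matrix, pacemaker, interferon and cell cycle genes, named long noncoding RNAs, small structured RNAs and markers of other cell types. They held 992 features. Lists were tested with cameraPR of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the lists, and with 10000 rotations of the statistics along the genome. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

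Features named in the text followed a rule set before the data were examined: features of Zfpm2, then the 12 higher and 12 lower features with the smallest adjusted p among those with an absolute log2 fold change of at least 1, with at most 1 per gene or cluster, then up to 4 members with the smallest adjusted p of each list that passed camera or had at least 2 called members, and of 3 lists on rhythm, transcription factors and atrial fibrillation in any case. The rule also asked that every FOG2_OE library lie beyond every WT library, which fitted values cannot show. Some features that the rule selects are not reported here. Features and clusters outside the rule, including the clusters described by their number of features, were chosen after their values were seen. Alternatives tried were other scales between the groups, a minimum of 20 fitted counts, other thresholds, leaving out the 100 most abundant features, other distances of 50 and 200 kb for lists and 20 and 500 kb for clusters, 1 feature per gene, and other set tests.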

Results

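The study asked how raising FOG2, a cofactor of GATA transcription factors encoded by Zfpm2, changed noncoding transcription in the atrium of the mouse heart. RNA was taken from the left atria of adult CD1 mice, an outbred stock, in 2 groups of 3 libraries each. One group overexpressed FOG2 (FOG2_OE) and the other was wild type (WT), and both had been kept without doxycycline for 1 week. Ribosomal RNA and polyadenylated RNA were depleted before sequencing, to leave transcripts without a poly(A) tail. The authors' deposited table listed 34518 features on the mm10 build, of which 34414 carried only an assembler identifier and 104 a gene symbol. The 6 sample columns held fitted values of the authors' model and not counts, so that no spread between replicates could be read from them. Values below are therefore given as the fold change and adjusted p of that table, with a standard error that was solved from its likelihood ratio. The effective library sizes implied by the table were 79663805, 72454816 and 84896198 reads for FOG2_OE replicates 1 to 3 and 71171501, 78393549 and 82240917 reads for WT replicates 1 to 3. The listed features held 5.25% of the effective library in FOG2_OE and 4.43% in WT. Most features were scarce: the median fitted count was 7.22 per library and 76.3% of features lay under 20.

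More noncoding features were called lower than higher with FOG2 overexpression, to an extent that depended on the scale between the groups. In the authors' deposited table, 402 features were higher and 1605 lower in FOG2_OE at an adjusted p under 0.05 (likelihood ratio test, Benjamini-Hochberg), so that 80.0% of the called features were lower. Intergenic features, 51.2% of all features, made up 179 of the higher and 985 of the lower calls in the authors' deposited table. Features listed antisense to a protein-coding gene, 28.0% of all, made up 97 and 394. Here and below, sense and antisense refer to the strand listed by the authors. The kit named in the labels does not mark strand, so that antisense transcription cannot be taken as measured. Exons of annotated long noncoding RNAs, 4.56% of all features, gave 31 higher and 82 lower calls in the authors' deposited table. Pseudogene exons (6 higher, 6 lower) and exons of protein-coding genes (8 and 10) were near balance in the authors' deposited table. Transcripts inside introns on the strand of the host gene gave 47 higher and 9 lower calls in the authors' deposited table, but 44 of the higher ones lay in Hdac9, a histone deacetylase gene, and outside it the class gave 3 higher and 9 lower. The median log2 fold change of all features in the authors' deposited table was -0.21. With the median ratio centred at 1 the recomputed calls were 560 higher and 1204 lower, or 68.3% lower, and made 322 clusters of higher and 433 of lower features at 100 kb, or 57.4% lower. The authors' test treats the dispersion of each feature as known. When the same likelihood ratio was referred to an F distribution with 4 residual degrees of freedom, 0 features passed (529 higher and 1927 lower at an unadjusted p under 0.05, smallest adjusted p = 0.252), and with 10 residual degrees of freedom 70 higher and 370 lower features passed. Only the reference distribution was changed. The ratios still rest on the authors' dispersions, so that any sharing between features in them remains. With 4 residual degrees of freedom even a likelihood ratio of 900 did not pass over the 34518 features. The 0 calls therefore cannot decide whether features changed.

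**Figure D1:**
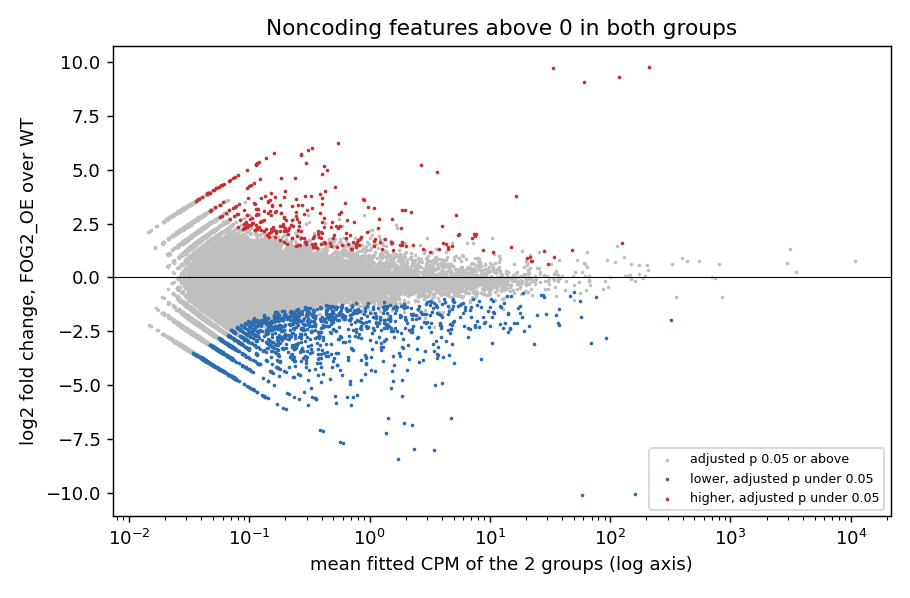
Log2 fold change of FOG2_OE over WT (y axis) against the mean fitted CPM of the 2 groups (x axis, log scale), 1 point per feature above 0 in both groups, from the authors' deposited table. Red points are called higher and blue points called lower at an adjusted p under 0.05; 4 red points with log2 fold changes above 9 stand apart at the upper right.

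Zfpm2 itself was followed first, since it checks the group labels. The feature MSTRG.29831, listed on the strand opposite to Zfpm2 and spanning chromosome 15 from 40752896 to 41103616 inside the gene body, had a log2 fold change of 9.74 (implied SE 0.31) and an adjusted p of 2.4e-117 in the authors' deposited table. Its fitted level was 416 CPM in FOG2_OE and 0.484 CPM in WT. The kit does not mark strand, so that reads of the sense mRNA and of an antisense transcript over the same bases could not be told apart. Upstream of the gene, 13 intergenic features lay 7.22 to 35.4 kb from the Zfpm2 transcription start site. All 13 had a log2 fold change under 0 in the authors' deposited table, with a median of -1.95, and 7 of them were called lower. With the median ratio centred at 1, MSTRG.29808 turned to 0.045 and MSTRG.29823 was no longer called (adjusted p = 0.064), and with 10 residual degrees of freedom MSTRG.29822 alone of the 7 passed (adjusted p = 0.0428). The most abundant of these, MSTRG.29818 (chromosome 15, 40628449 to 40636927), had a log2 fold change of -1.84 (implied SE 0.37, adjusted p = 0.00011) in the authors' deposited table (adjusted p = 0.0537 with 10 residual degrees of freedom), with fitted levels of 1.75 CPM in FOG2_OE and 6.27 CPM in WT. Summed over the 13 features, the fitted level was 3.41 CPM in FOG2_OE and 12.7 CPM in WT. The 13 lie close together and are all listed on the same strand. Whether they are pieces of 1 transcript was not tested, so that they cannot be taken as separate observations.

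Among the features that rose, MSTRG.83493, which overlaps exons of the long noncoding RNA Gm47326 antisense to Endod1 (chromosome 9, 14340850 to 14359031), went from 0.371 CPM in WT to 236 CPM in FOG2_OE, with a log2 fold change of 9.31 and an adjusted p of 3.2e-193 in the authors' deposited table. MSTRG.66128, antisense to 2900026A02Rik (chromosome 5, 113203355 to 113217757), went from 0.225 to 122 CPM, and its adjusted p was 4.9e-111 in the authors' deposited table. MSTRG.85269 overlaps an exon of Hcn4 on the gene's strand (chromosome 9, 58861118 to 58864170). Hcn4 encodes the main channel of the pacemaker current, and this feature had a log2 fold change of 5.22 (implied SE 0.46, adjusted p = 8.1e-23) in the authors' deposited table. MSTRG.80550, 51.3 kb from the start of the neuropeptide Y receptor gene Npy1r, rose from 2.25 to 30.8 CPM (log2 fold change 3.77 in the authors' deposited table). MSTRG.79359 antisense to Agpat5 (log2 fold change 4.91 in the authors' deposited table), MSTRG.20656 12.4 kb from Ttc7b (5.99) and MSTRG.20520 in an Hdac9 intron (4.18) also rose. The remaining 4 of the 12 were MSTRG.89455 near 1110012L19Rik, MSTRG.69033 antisense to Tbxas1, MSTRG.87881 in the long noncoding RNA AU023762 and MSTRG.33515 109 kb from Bcl6, with log2 fold changes of 2.90 to 5.33 in the authors' deposited table. In WT, MSTRG.20656 and MSTRG.89455 stood at 0.0087 and 0.0129 CPM, no more than 3 counts over the group. Their folds are therefore imprecise (implied SE 1.09 and 0.95).

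Among those that fell, MSTRG.64113 antisense to Kcnip4, a gene of a potassium channel interacting protein (chromosome 5, 48782298 to 48790843), had the smallest adjusted p, 7.9e-41 in the authors' deposited table. Its fitted level was 0.0254 CPM in FOG2_OE and 6.82 CPM in WT (log2 fold change -7.98, implied SE 0.69, from the authors' deposited table). MSTRG.11505, 7.06 kb from the start of the atrial myosin light chain gene Myl7 (chromosome 11, 5889729 to 5891720), had a log2 fold change of -5.49 (implied SE 0.52, adjusted p = 4.9e-22) in the authors' deposited table. MSTRG.13861 lay 189 kb from Myocd, which encodes the muscle coactivator myocardin, and fell from 15.7 to 1.15 CPM (log2 fold change -3.77 in the authors' deposited table). The long noncoding RNA AC118724.1, 49.2 kb from Vldlr, was the most abundant of the 12, with 61.7 CPM in WT and 13.3 CPM in FOG2_OE (MSTRG.43023, log2 fold change -2.22 in the authors' deposited table). MSTRG.48971 antisense to Sema6d, MSTRG.87406 antisense to Tmem108 and MSTRG.67235 antisense to Cyp3a13 fell as well, with log2 fold changes of -4.74, -6.52 and -3.59 in the authors' deposited table. The other 5 were intergenic or antisense to genes with a provisional name, and lay nearest to Gatb, Micu3, Med13l, Irf8 and 1700018B08Rik (MSTRG.53424, MSTRG.80033, MSTRG.66362, MSTRG.82594 and MSTRG.82670), with log2 fold changes of -8.43 to -4.90 in the authors' deposited table. Fold changes this large rest on few counts in the lower group.

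Changed features lay next to each other along the genome. Of the 2007 features called in the authors' deposited table, 977 (48.7%) had a nearest neighbour within 100 kb that was called in the same direction, against a mean of 75.9 and a highest value of 115 in 1000 shuffles of the calls (permutation p = 0.001, one-sided, the smallest that 1000 shuffles can give). Grouped at 100 kb, the calls of the authors' deposited table made 231 clusters of higher and 593 clusters of lower features. The largest, with 81 lower features, ran on chromosome 2 from 107315392 to 107798274, nearest to the potassium channel gene Kcna4, and the 113 listed features of this interval, called or not, summed to 60.2 CPM in FOG2_OE and 263 CPM in WT. The intervals were chosen by their calls, and the folds that follow are sums over all listed features of an interval. A cluster of 62 lower features covered chromosome 11 from 65405857 to 65650034 between Myocd and Map2k4, an interval 9.63-fold lower. On chromosome 1, the interval of a cluster of 44 features near Tnfsf4 and Tnfsf18 was 28.6-fold lower. That of a cluster of 38 features near Rgs2, Rgs13 and Rgs1, which encode regulators of G protein signalling, was 12.6-fold lower. Of 23 features inside Kcnip4, 19 were called lower in the authors' deposited table, and these made up an interval that was 182-fold lower in sum. Among higher clusters, 44 features lay in introns of Hdac9 (chromosome 12, 34591897 to 34778120), and the interval was 3.39-fold higher. A cluster of 8 features near Npy1r was 13.8-fold higher. The interval around Hcn4 (chromosome 9, 58816624 to 58867659), which begins upstream of the gene and runs past its end, held 8 features, 6 of them called, and was 20.9-fold higher (33.1-fold over the 6 called features alone). Most of this sum was MSTRG.85269 over an Hcn4 exon, with 5.22 of 6.82 CPM in FOG2_OE. Whether that feature held reads of Hcn4 mRNA was not tested.

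**Figure D2:**
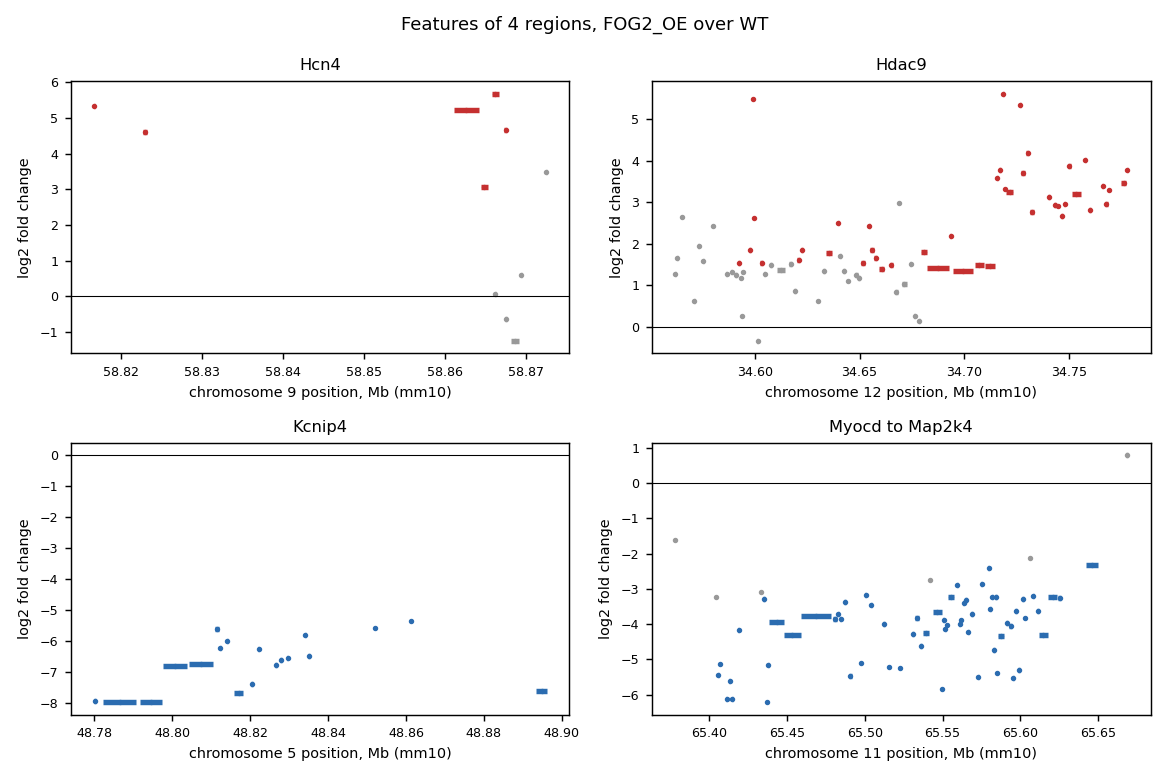
Log2 fold change of FOG2_OE over WT (y axis) of every listed feature in 4 regions (x axis, mm10 position in Mb), from the authors' deposited table; bars span the feature, points mark its middle, red is called higher, blue called lower and grey not called. The Hcn4 cluster holds 6 higher features and the Hdac9 cluster 44, while the cluster antisense to Kcnip4 holds 19 lower features and that between Myocd and Map2k4 holds 62.

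Gene lists were fixed before the data were examined, and a feature was linked to a gene when it overlapped it or, for intergenic features, when the nearest transcription start site lay within 100 kb. Lists were tested with limma's preranked camera on the signed root of the authors' likelihood ratio, with a preset correlation of 0.01, and beside it with rotations of the statistics along the genome, which keep neighbouring features together. On simulated statistics with correlated neighbours, camera passed 31.7% of 180 unmoved lists at p under 0.05 and the rotation test 6.11%, so that the rotation p is given beside each camera call. Of the 25 lists, 6 passed an adjusted p of 0.05 in camera and 3 of them in the rotation test.

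Calls among features of pacemaker and conduction genes were on the higher side. The list had 21 features from Hcn4 (11), Cpne5 (9) and Tbx3 (1), and 8 were called higher and 0 lower in the authors' deposited table (11 and 2 adjusted over the list alone). The calls were 6 features of Hcn4 and 2 of Cpne5, a marker of the conduction system; other features reached -1.25 at Hcn4 and -1.47 at Cpne5, and that of Tbx3 stood at -0.56 (log2 fold changes in the authors' deposited table). The median log2 fold change of the list in the authors' deposited table was 1.86, or 2.08 relative to the median of all features (camera adjusted p = 1.7e-13, rotation adjusted p = 0.044). Besides MSTRG.85269, MSTRG.85262 and MSTRG.85258 just past the end of Hcn4 and MSTRG.85266 0.234 kb from its start rose, by 5.68, 3.07 and 4.62 on the log2 scale in the authors' deposited table. Whether MSTRG.85269, over an exon, and the features just past the gene's end held reads of Hcn4 mRNA was not tested. In WT, MSTRG.85262 stood at 0.0087 CPM, under the floor of 3 counts over the group (implied SE 1.10). Without Hcn4 the camera adjusted p was 0.0023, but this rests on 10 features, 9 of them of Cpne5, for which the rotation test was not run.

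Atrial muscle genes gave lower calls only, and the list did not pass once neighbours were kept together. Of 99 features, 15 were called lower and 0 higher in the authors' deposited table (24 and 4 adjusted over the list alone). They belonged to Kcnj3 (5), which encodes a channel of the acetylcholine-activated potassium current, Myl7 (3), the calcium pump regulator Sln (3), Clu (2), Dkk3 (1) and Fgf12 (1). MSTRG.46334 and MSTRG.46340, antisense to Kcnj3, had log2 fold changes of -2.24 and -2.18, and MSTRG.11504 near Myl7 of -5.13, in the authors' deposited table. MSTRG.11504 (chromosome 11, 5889618 to 5891111) overlaps MSTRG.11505 and is listed on the other strand. The kit does not mark strand, so that these Myl7 calls cannot be taken as separate observations. The median of the list was -0.70, or -0.49 relative to the median of all features. The camera adjusted p was 0.0023 and the rotation adjusted p 0.11. Without Myl7 the camera adjusted p was 0.067 and without Kcnj3 0.0519, and with a preset correlation of 0.1 and all genes the adjusted p was 0.557. The 20 features of Kcna5 had a median log2 fold change of 0.85 in the authors' deposited table, with none called.

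The list of rhythm channels and calcium handling genes went both ways. Of its 161 features 9 were called higher and 22 lower in the authors' deposited table (15 and 32 adjusted over the list alone), and its camera adjusted p was 0.66. The higher ones included 6 features of Hcn4 and 1 of Ryr2. Lower calls in the authors' deposited table included 5 features of the calcium pump gene Atp2a2, 5 of Kcnj3, 3 each of Sln and Ryr2, and 1 each of Cacna1c, Kcnh2 and Camk2d.

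Of 80 features of cardiac transcription factors 2 were called higher and 9 lower in the authors' deposited table (3 and 12 adjusted over the list alone; camera adjusted p = 0.66). The higher ones were the Zfpm2 feature and MSTRG.27735 antisense to Gata4 (log2 fold change 3.17 in the authors' deposited table), the latter named after its values were seen. The lower ones were 7 features upstream of Zfpm2, MSTRG.39407 near Gata6 and MSTRG.5056 antisense to Prrx1 (log2 fold changes -1.63 and -3.43 in the authors' deposited table), the last 2 also named after their values were seen. As given above, the 7 upstream features cannot be taken as separate observations. With the median ratio centred at 1 the Prrx1 feature was no longer called (adjusted p = 0.053). With 1 feature per gene, where MSTRG.29831 stands for Zfpm2, the list passed with the direction reversed to higher (camera adjusted p = 0.0014). Features of genes named for atrial fibrillation loci gave 9 higher and 5 lower calls among 184 in the authors' deposited table (9 and 5 adjusted over the list alone; camera adjusted p = 0.48), with Hcn4 giving 6 of the higher.

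Sarcomere genes had 2 higher and 8 lower features of 170 in the authors' deposited table (2 and 9 adjusted over the list alone; camera adjusted p = 0.73). The lower ones included 3 features of Myl7, given above with the atrial muscle genes, of which MSTRG.11504 and MSTRG.11505 overlap. With 1 feature per gene the sarcomere list passed on the lower side (camera adjusted p = 0.014). Stress and fetal muscle genes had 2 higher and 3 lower features of 88 in the authors' deposited table, the same numbers adjusted over the list alone (camera adjusted p = 0.66). MSTRG.62122 and MSTRG.62113, 1.70 and 2.85 kb from Nppb, which encodes the B-type natriuretic peptide, had log2 fold changes of -3.78 and -3.83 in the authors' deposited table. They were the only features of Nppb called, and all 15 of its features had a median of 0.42 in the authors' deposited table. MSTRG.19964 antisense to Actn1 rose (adjusted p = 1.9e-05 in the authors' deposited table). In WT it stood at 0.0043 CPM, under the floor of 3 counts over the group (implied SE 1.54). Mitochondrial and fatty acid oxidation genes had 2 higher features, MSTRG.68047 and MSTRG.68058 near Pdk4, and 2 lower ones, MSTRG.31550 antisense to Ppara and MSTRG.80188 near Slc25a4, of 58 in the authors' deposited table, again the same over the list alone (camera adjusted p = 0.96). With the median ratio centred at 1 MSTRG.80188 was no longer called (adjusted p = 0.112).

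Extracellular matrix and fibrosis genes had a median log2 fold change of 0.82 over 46 features in the authors' deposited table, or 1.03 relative to the median of all features (camera adjusted p = 1.4e-05, rotation adjusted p = 0.044). With a preset correlation of 0.1 the list did not pass (adjusted p = 0.103). Only 2 features passed on their own, MSTRG.86303 and MSTRG.86283 at the start of the collagen gene Col12a1 (log2 fold changes 3.38 and 4.49 in the authors' deposited table), and 3 did adjusted over the list alone. In WT, MSTRG.86283 stood at 0.0043 CPM, under the floor of 3 counts over the group (implied SE 1.56). Interferon response genes passed camera (adjusted p = 0.0028) with 1 called feature of 18 in the authors' deposited table, MSTRG.35072 inside Mx2 (1 over the list alone), and did not pass the rotation test (adjusted p = 0.091). Named long noncoding RNAs passed camera (adjusted p = 1.5e-05) and did not pass the rotation test (adjusted p = 0.11). Of their 101 features 64 belonged to Pvt1, and 3 were called higher in the authors' deposited table, as over the list alone: MSTRG.30732 and MSTRG.30360 in Pvt1 and MSTRG.80406 in Hand2os1, which stood at 0 in WT and was at least 12.4-fold higher (floor of 3 counts over the group).

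Features linked to markers of other cell types were tested as well. These features lie in or near the marker genes, in RNA depleted of polyadenylated transcripts. They do not measure the marker mRNA, so that these lists cannot show whether the tissue content differed. The lung epithelium list held 4 features, and 2 of them, MSTRG.26724 and MSTRG.26725 within 6.27 kb of the surfactant gene Sftpa1, were higher in the authors' deposited table, as over the list alone (log2 fold changes 5.70 and 5.53; camera adjusted p = 0.00014, rotation adjusted p = 0.044). In WT these 2 features stood at 0.0086 and 0.0043 CPM, under the floor of 3 counts over the group (implied SE 1.15 and 1.52). The list did not pass with ranks (adjusted p = 0.311), and its call rests on these neighbouring features of 1 gene. The features at the surfactant gene Sftpb and at Hopx had log2 fold changes of -0.06 and -0.77 in the authors' deposited table and were not called. Lists for fibroblasts, endothelium, smooth muscle and pericytes, macrophages, lymphocytes, neutrophils, erythroid cells, epicardium and mesothelium, adipocytes, and Schwann cells and neurons had camera adjusted p-values of 0.15 to 0.96. In these lists 1 feature was called higher, MSTRG.43342 antisense to Acta2, and 2 lower in the authors' deposited table, at Notch3 (MSTRG.36961) and Npr3. MSTRG.43342 stood at 0.0043 CPM in WT, also under the floor of 3 counts over the group (implied SE 1.53). The erythroid list rested on Alas2 alone, the epicardial list on 2 genes, and the lymphocyte, neutrophil and adipocyte lists on 3 genes each. With the median ratio centred at 1 MSTRG.36961 was no longer called (adjusted p = 0.21). Ventricular muscle genes (1 lower of 13), cell cycle genes (1 higher, near Aurkb, and 1 lower, antisense to Bub1b, of 15) and small structured RNA genes (0 of 6) did not pass either, with camera adjusted p-values of 0.66 for each and calls from the authors' deposited table. Adjusted over the list alone, the lists of cell types other than lung gave 1 higher and 1 lower call, ventricular genes 1 lower, and cell cycle genes 1 higher and 1 lower. Lists for atrial fibrillation loci, stress, endothelium, smooth muscle, neutrophils, adipocytes and the cell cycle had a median under 0 while camera, which compares with all features, put them on the higher side, and none of these passed.

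**Figure D3:**
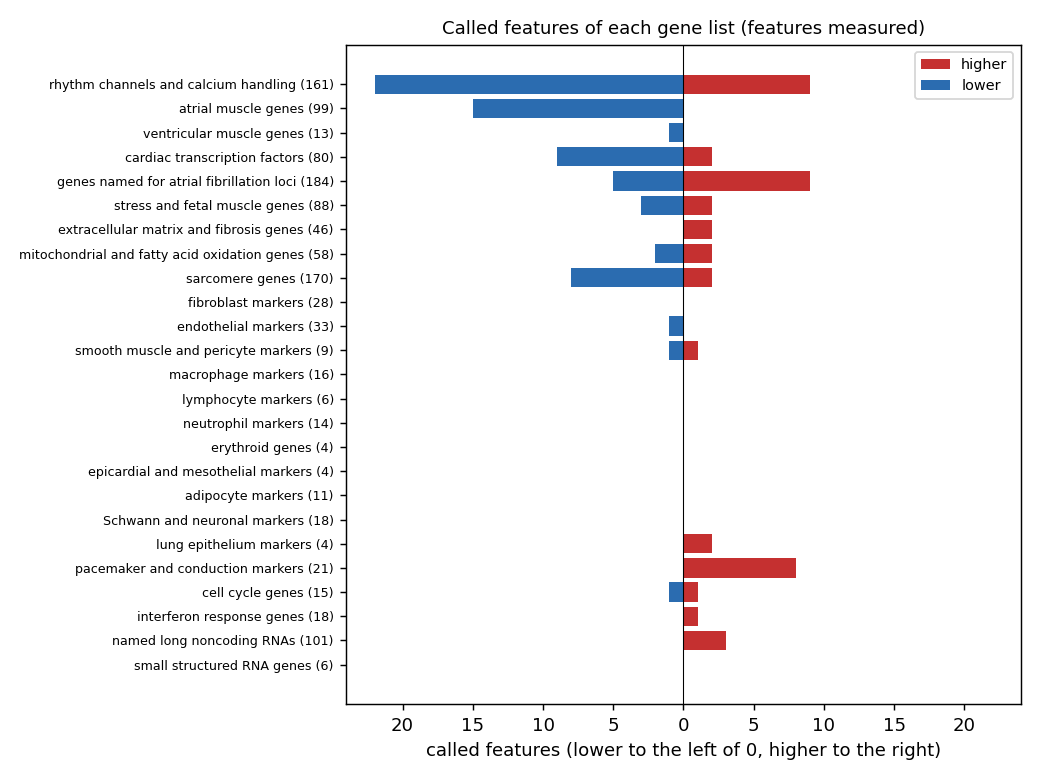
Number of features called higher (red, right of 0) and lower (blue, left of 0) in the authors' deposited table for each of the 25 gene lists (y axis, with the number of measured features in parentheses). Rhythm channels gave 9 higher and 22 lower features, atrial muscle genes 15 lower and none higher, and pacemaker and conduction markers 8 higher and none lower.

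A few features took much of the signal of the table. The 4 most abundant ones held 48.7% of the fitted signal in FOG2_OE and 34.8% in WT, and none of the 4 was called in the authors' deposited table. Intergenic features held 51.5% of the signal in FOG2_OE and 49.0% in WT, and features antisense to protein-coding genes 20.8% and 17.8%. Without the 10 most abundant features the intergenic difference turned (37.1% and 37.9%) and the antisense one shrank (21.7% and 20.6%). These shares come from fitted values and have no replicate error.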

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

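Settings on the scale by table total, the F distribution, rotation, a correlation of 0.1, ranks and left-out genes were chosen after seeing the data. No paired analysis was possible because the sample columns hold fitted values with no spread between replicates. For the same reason other count tools, library size without composition scaling, a run with no filter, left-out replicates, fry, an estimated correlation and other splits of the 6 libraries were not run, so that whether chance or 1 library drives a call was not tested. The calls of 402 higher and 1605 lower features became 231 and 890 with at least 20 fitted counts, where fewer features were tested, 231 and 593 when clusters were counted once, 70 and 370 with 10 residual degrees of freedom, and 0 and 0 with 4, a test in which the smallest adjusted p was 0.252. With 4 residual degrees of freedom even a likelihood ratio of 900 did not pass, so that the 0 calls cannot decide whether features changed. Higher features numbered 620 at an adjusted p under 0.1, and lower ones 2461 with the total of the table equal between groups. The feature listed antisense to Zfpm2 (log2 fold change 9.74, which this setting cannot alter) lost its call at 4 residual degrees of freedom (adjusted p = 0.252) and passed in all other settings run. Without the 10 most abundant features the intergenic share was 37.1% in FOG2_OE and 37.9% in WT, and the antisense share 21.7% and 20.6%. Adjusted p-values of lists that no longer passed were, with a correlation of 0.1, 0.557 for atrial muscle, 0.103 for matrix, 0.158 for interferon and 0.207 for named long noncoding RNAs; under rotation, 0.112 for atrial muscle, 0.0906 for interferon and 0.112 for named long noncoding RNAs; with 1 feature per gene, 0.0936 for interferon and 0.253 for named long noncoding RNAs; without their most influential gene, 0.0674 for atrial muscle (Myl7; 0.0519 without Kcnj3), 0.188 for interferon (Mx2) and 0.631 for named long noncoding RNAs (Pvt1); and with ranks, 0.311 for lung epithelium. With 1 feature per gene sarcomere genes passed, lower (0.0140), and cardiac transcription factors passed with the direction reversed to higher (0.00139), where the Zfpm2 antisense feature stands for its gene. The pacemaker list passed in all settings run, though rotation was not run without Hcn4. Of 79 other named features, 76 kept their side of the threshold with the total of the table, 74 with the centred median, and 60 with 10 and 20 with 4 residual degrees of freedom. The cause of changes not named here was not tested. The median implied standard error was 0.96 for features under 10 fitted counts and 0.26 for those of at least 1000.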

Other observations

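The tests in this part were chosen after the results were seen, except that the calls with the median ratio centred at 1, the calls without the 100 most abundant features and the counts of clusters were set beforehand; the limits and intervals put on them were not. Several abundant transcripts outside the rule for named features changed. MSTRG.7524, the long noncoding RNA D830005E20Rik antisense to the calcium release gene Trdn, fell from 511 to 130 CPM (log2 fold change -1.98, adjusted p = 2.4e-07 in the authors' deposited table). MSTRG.17860, in Gm48898 on the strand of the growth factor gene Gdf7, rose from 62.6 to 190 CPM (log2 fold change 1.60 in the authors' deposited table). Near Rtl1 on chromosome 12, in the imprinted region known for paternally expressed Dlk1 and maternally expressed noncoding RNAs, 7 features between 109580322 and 109711797 were called higher, and the 10 listed features of this interval were 2.55-fold higher in sum. Xist (MSTRG.90114) stood at 701 CPM in both groups.

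MSTRG.82875 and MSTRG.82877, antisense to Def8 (chromosome 8, 123426279 to 123434056), had log2 fold changes of -10.03 and -10.08 in the authors' deposited table, with 324 and 116 CPM in WT, and a biological coefficient of variation of 115% and 112%, against a median of 21.5% for features of at least 1000 fitted counts. MSTRG.82877 (123428911 to 123429972) lies inside MSTRG.82875 on the same listed strand, so that they cannot be taken as separate observations.

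The excess of lower calls was weighed first. Leaving out the 100 most abundant features moved the scale between the groups by -0.0159 on the log2 scale, but the small share of the library that the table holds fixes this outcome (at most 0.0777), and abundant RNA outside the table was not tested. Counting clusters, 72.0% (95% Wilson interval 68.8 to 74.9) were lower, against 80.0% of the called features. A few long transcripts split into many features may thus account for part of the excess. At the deposited scale they do not account for all of it. Centring the median ratio at 1 left 57.4% of clusters lower (53.8 to 60.8), still above 50; an earlier form of this test counted features, 68.3% lower (66.0 to 70.4), against a limit of 60, which the interval over clusters would not have cleared. The scale therefore may account for much of the excess, and a shift of -0.45 would balance the feature calls at 918 higher and 973 lower, so that a general effect of FOG2 on noncoding transcription stays an untested hypothesis.

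The runs of like-changed neighbours were weighed next. Of 78 clusters with at least 5 features, 63 lay wholly on 1 strand, against a mean of 38.9 and a highest value of 53 for runs of as many unchanged neighbours (permutation p = 0.001, one-sided, the smallest that 1000 draws can give). An earlier form, over pairs of neighbours, gave 96.3% on the same strand against 81.6% for unchanged pairs. The strands are those of the table, and the kit does not mark strand, so that these values do not decide whether the clusters are pieces of 1 long transcript listed as separate features. That and a regulatory domain acting on its whole length cannot be told apart, and counts of features may overstate the number of separate changes.

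The loci of Zfpm2, Sesn3 to Endod1 and 2900026A02Rik held the 4 features with log2 fold changes above 8 and at least 50 CPM in FOG2_OE, with biological coefficients of variation of 17.6% to 25.4%. Within 1 Mb of the latter loci 1 of 63 features was called higher (exact 95% interval 0.040% to 8.53%), and the medians of their log2 fold changes in the authors' deposited table were -0.02 around Sesn3 to Endod1 and 0.36 around 2900026A02Rik, against -0.21 for all features. Only 11% of simulated 2-fold changes were called, though they were planted in features with at least 20 expected counts. The values around the loci therefore do not decide whether a change spread along the chromosome. A hypothesis is that these features may hold RNA of the introduced constructs or of their insertion sites, which would not be regulation by FOG2. At Zfpm2, 0 of 2 other features inside the gene were called higher, too few to decide, so that transgene RNA and antisense transcription of the native gene cannot be told apart. A strain variant carried by one group was not tested.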
